A study of Arabidopsis thaliana with 24 samples.

How the data were processed

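The series holds 24 one-colour arrays of Arabidopsis thaliana seedlings in 8 groups of 3. Total RNA was extracted with silica columns, labelled with Cy3 and hybridised to an Agilent Arabidopsis expression array, per the labels' protocols. Groups and replicate numbers were taken from the submitters' sample labels, which describe the replicates as 3 independent experiments. Arrays of the same replicate number were scanned on the same day, and each of the 3 scan days had 2 slides of 4 arrays. In each experiment 1 slide carried the 4 groups at 0 h and the other the 4 groups with flg22, per the file headers. Position on the slide was fixed for each group and cannot be told apart from it. No arrays of seedlings kept for 2 h or 24 h without flg22 were analysed here, nor was the water control that the protocols name.

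The scanner files hold spot intensities on a linear scale, which per the file headers were read with Agilent Feature Extraction 10.7.3.1, with a design file annotated to the TAIR10 gene models. The processed signal used here had been background-subtracted and corrected for spatial trends within the array by that software, per the file headers, and had not been scaled between arrays. The deposited value table of the series holds log2 values for 43553 probes, with medians between 9.75 and 9.76 in its 24 columns. Each column ranked the probes as the processed signal of its array did (rank correlation 1.0). In the brighter part of the probes its values differed from log2 of that signal by a median of -0.725 to 0.438, depending on the array. Values were not centred per gene. How the authors normalized this table is not given in the sources used here. The submitters' processing notes name limma without a version. A set of 50 probes, each printed 5 times, was not in the table.

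Each array had 45220 spots. The 1417 control spots were left out, as were spots that Feature Extraction had marked as non-uniform or population outliers (11 to 622 per array). Saturated spots (0 to 3 per array) were kept. The remaining 43803 gene spots represented 43603 probes, and the spots of a probe printed 5 times were averaged on the log2 scale. The accession of each probe was matched, without its version, to the gene table of the reference assembly TAIR10.1, which gave 34348 probes with 1 gene and 0 with several. The other 9255 probes kept the accession of the array file and are unnamed. The 75th percentile of the processed signal was subtracted from each array on the log2 scale. A probe was tested if it was well above background on all 3 arrays of at least 1 of the 8 groups, which 34062 probes were. Where a gene had several such probes, the probe with the highest mean over the 24 arrays was used. This left 25740 genes, 21111 of them with a locus of the reference table and 8889 with a symbol. For 6430 tested genes with 2 or more probes, probes passed in opposite directions in 33 and 42 genes at 2 h of flg22 (after acetone and oxo-C14-HSL), 6 and 6 at 24 h, and 8 and 6 between 24 h and 2 h. None did in the other comparisons.

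Groups were compared with limma (lmFit and eBayes) in 1 model of all 24 arrays with 8 group means and no block, which left 16 residual degrees of freedom, with 1.90 prior degrees of freedom. Sharing the spread among all groups assumes that they vary alike. There were 16 comparisons: each flg22 time against 0 h and 24 h against 2 h within a pretreatment, each AHL against acetone and the AHLs against each other at 0 h, oxo-C14-HSL against acetone at each flg22 time, and the differences between the flg22 responses at 2 h and 24 h. P-values were adjusted by the Benjamini-Hochberg method within a comparison, and an adjusted p under 0.05 was the threshold. Adjusted p-values of genes are limma's throughout, and intervals are 95% intervals from the same fit. Where a gene was not well above background on any of the 3 arrays of the dimmer group, the fold change is given as a lower limit. It is the mean of the brighter group against the mean of the higher of the lowest well-above-background signal and the gene's own signal on each array of the dimmer group.

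A set of 20 gene lists held 385 genes, of which 380 were tested, and no gene stood in more than 1 list. They covered the early flg22 response, pattern receptors and signalling, salicylic acid, jasmonate and oxylipins, ethylene and defensins, phenylpropanoids with lignin and callose, camalexin and indole glucosinolates, and aliphatic glucosinolates. The others were xenobiotic detoxification, AHL uptake and perception candidates, photosynthesis, root markers, auxin response, cell cycle, circadian clock, flavonoids and anthocyanins, heat shock, low oxygen, senescence and carbon starvation, and reference genes. None was chosen on these samples. Lists were tested against the 25413 genes with a value on all 24 arrays, using limma's camera with its preset inter-gene correlation of 0.01, adjusted over the 20 lists, and again with a correlation estimated for each list. Members past the threshold were counted over all genes and when adjusted over the list alone. Genes were named by a rule: the 10 largest increases and the 10 largest decreases of a comparison among genes with a symbol that passed, changed in the same direction in all 3 same-numbered pairs of arrays and were well above background on all 3 arrays of the higher group. Where fewer than 5 passed, the 5 with the smallest p were named as not passing. In each list the 4 members with the largest absolute log2 difference could be named, and 16 defence and detoxification genes (FRK1, WRKY22, WRKY29, FLS2, CYP81F2, PR1, ICS1, EDS1, PAL1, CAD5, GSL5, LOX2, PDF1.2a, GSTU24, CYP81D11 and FAAH) in every comparison. The groups, tests, lists, naming rule and alternatives were fixed before the data were examined, except where a choice is said to have been made later.

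Given the labels and scan days, the replicate numbers were taken to pair the arrays. The deviations of same-numbered arrays from their group means correlated with a median r of 0.421 across genes (range -0.113 to 0.767, above 0.1 in 72 of 84 pairs), against -0.249 for arrays of different numbers. The median was 0.516 on the same slide and 0.355 on different slides, and 19 of 24 arrays correlated best with an array of their own number. A fit with the experiment as a fixed block (14 residual degrees of freedom) was an alternative.

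The other alternatives were quantile normalization, the deposited value table, no filter on dim probes, a filter of all 24 arrays above background, a floor at the lowest well-above-background signal, slide as a random block (duplicateCorrelation) or, for groups that share slides, as a fixed block, only the arrays compared, eBayes with trend and robust, the mean over the probes of a gene, an additional limit of 2-fold, and leaving out each array or each experiment. Normexp (offset 50) followed by quantile normalization was run on the median spot signal, a choice made after the data were seen, because the mean spot signal planned for it was not among the columns. For correlations between comparisons that share control arrays, unchanged groups were simulated 100 times.

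The steps were tested on simulated data in which 200 of 25740 genes were changed. For oxo-C14-HSL against acetone at 0 h, changes of 0.5, 1 and 2 on the log2 scale were recovered in 23.9%, 65.7% and 86.4% of cases, and 1 of 118 calls fell on an unchanged gene. With the block the shares were 44.8%, 74.6% and 92.4%, with 8 false calls of 149. Computations used R 4.3.3 with limma 3.58.1 and statmod 1.5.0, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.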

Results

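Gene expression was measured in Arabidopsis thaliana seedlings that had been kept for 3 days with an N-acyl homoserine lactone (AHL) or with the solvent acetone. AHLs are signal molecules that many Gram-negative bacteria use in quorum sensing. The seedlings had grown for 14 days on plates before they were moved to liquid medium. Each AHL was given at 6 µM. C6-HSL carries an unsubstituted hexanoyl chain, oxo-C10-HSL a 3-oxodecanoyl chain and oxo-C14-HSL a 3-oxotetradecanoyl chain on the same L-homoserine lactone ring. Seedlings pretreated with acetone or oxo-C14-HSL were then given 100 nM flg22, the peptide of bacterial flagellin that plants perceive through the receptor kinase FLS2, for 2 h or 24 h. The design asks how seedlings respond to AHLs of different structure and whether oxo-C14-HSL alters their response to flg22. The 8 groups were acetone, C6-HSL, oxo-C10-HSL and oxo-C14-HSL at 0 h, and acetone and oxo-C14-HSL at 2 h and at 24 h of flg22. Each had 3 arrays.

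Of the 43803 gene spots on each array, between 71.4% and 86.5% were well above background. The 75th percentile of the processed signal lay between 3392 and 7566 intensity units, against a median local background of 21 to 25 units. The number of arrays, 3 per group, limited precision, and the median standard error of a log2 difference between 2 groups was 0.157 (0.142 with the experiment as a block). Arrays of a group correlated with r from 0.972 to 0.993 across genes, which are not independent replicates. Principal component 1 held 54.4% of the variance and separated the 0 h arrays from those at 2 h of flg22, with the 24 h arrays between them. Component 2 held 17.3% and set the 24 h arrays apart from the 2 h arrays. The 4 arrays of experiment 1 at 0 h stood apart from those of experiments 2 and 3 on both components (-38.4 to -32.3 on component 1, against -83.9 to -68.6). The oxo-C10-HSL group had the largest median residual spread (SD 0.218, against 0.134 for oxo-C14-HSL at 0 h).

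**Figure D1:**
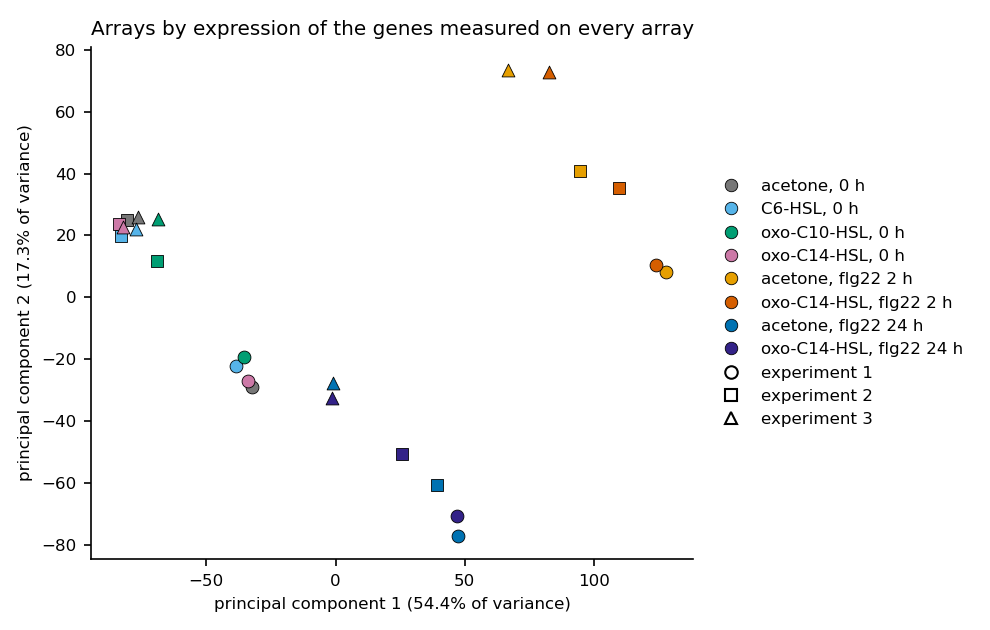
Each point is 1 of the 24 arrays, placed by its scores on principal components 1 and 2 (arbitrary units), coloured by group and shaped by experiment. The 0 h points of experiment 1 lie apart from the other 0 h points.

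After 2 h of flg22, many defence genes were higher in acetone-pretreated seedlings. FRK1, a receptor kinase gene used as a marker of early flg22 signalling, rose by 5.82 ± 0.21 (log2 difference ± SE, 3 arrays per group), and the transcription factor genes WRKY22 and WRKY29 rose by 4.01 and 3.63. CYP81F2, whose product hydroxylates indole glucosinolates, rose by 5.40, PROPEP3, the precursor of a danger peptide, by 6.25 ± 0.27, and the flg22 receptor gene FLS2 itself by 1.57. MYB111, a regulator of flavonol synthesis, fell (-4.86 ± 0.33), as did the morning clock gene CCA1 (-2.32 ± 0.14). In all, 12539 of 25740 genes passed the threshold in limma (5313 higher and 7226 lower), 4398 of them by at least 2-fold. Among the genes with the largest increases were the nitrate transporter gene NRT2.6 (at least 237-fold) and the cytochrome P450 genes CYP82C3 (at least 103-fold) and CYP82C2 (at least 54.2-fold). These and PP2-B14 (at least 39.5-fold) were not well above background on any acetone array at 0 h. The peroxidase gene PER4 rose by 8.30, with 2 of the 3 arrays at 0 h well above background. The glutamate receptor gene GLR2.9 rose by 6.71 with 1 such array, BGLU27 by 7.4 with 1, and FAMT and PP2-B13 by 6.98 and 6.68. The largest decreases after MYB111 were those of GASA6 (-4.17), the lipid transfer protein gene LTP4 (at least 7.2-fold), the B-box gene BBX31 (-4.14), ASG4 (-4.13) and the GATA factor gene CGA1 (-4.1). ARD3 (-4.09), ABCF2 (-3.52), SAD6 (-3.42) and the pyruvate decarboxylase gene PDC1 (-3.21) followed. Each of these genes changed in the same direction in all 3 experiments, and the largest adjusted p among them was 0.00732, for LTP4 in limma.

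The list of early flg22 response genes was, with the camalexin list, the most strongly changed of the 20 lists at 2 h after acetone. Of its 28 members, 25 rose and 1 fell (26 and 1 when adjusted over the list alone), with ZAT11 at 5.51 and WRKY40 at 4.42. Its mean difference was 2.82 (camera, adjusted p = 0.0135 with an estimated correlation). All 14 pattern receptor and signalling genes rose (14 adjusted over the list alone; adjusted p = 0.0135 with an estimated correlation). They included the chitin receptor genes LYK4 (3.45), CERK1 (2.38) and LYK5 (2.14) and the kinase gene BIK1 (1.97). In the camalexin and indole glucosinolate list 16 of 18 rose and 1 fell, the same numbers when adjusted over the list alone (adjusted p = 0.00692 with an estimated correlation). The methyltransferase genes IGMT2 and IGMT1 rose by 6.05 and 4.21, and CYP71A13 and CYP71A12, which act towards camalexin, by 5.06 and 4.53. Salicylic acid genes rose in 19 of 24 cases (19 adjusted over the list alone), among them CBP60g (2.88), NIMIN1 (2.86), GRX480 (3.16) and ALD1 (at least 8.32-fold). ICS1, whose product makes the precursor of salicylic acid, rose by 2.42, while the salicylate marker PR1 had -0.71 with a limma adjusted p of 0.575. Jasmonate and oxylipin genes rose in 15 and fell in 2 of 28 cases (the same counts when adjusted over the list alone). Among them were the repressor genes JAZ5 (3.24) and JAZ8 (at least 19.0-fold) and the biosynthesis genes LOX4 (3.96) and AOC1 (3.43). The ethylene and defensin list had 8 members higher and 3 lower of 18 (8 and 4 adjusted over the list alone). ACS2 (3.47), ORA59 (3.29), ERF1 (3.23) and ACS8 (at least 3.02-fold) rose, whereas PDF1.2a had 0.48 and did not pass. In the phenylpropanoid list 20 rose and 2 fell of 28 (the same when adjusted over the list alone). Among those that rose were PRX52 (5.59, 1 array at 0 h above background), CCR2 (3.74), PAL1 (1.80), and the callose synthase gene GSL5 (0.85). Detoxification genes rose in 25 and fell in 4 of 40 cases (25 and 5 adjusted over the list alone). Members that rose included ABCG40 (5.78), GSTU12 (5.46), GSTU11 (4.11), CYP81D8 (3.71) and CYP81D11 (2.9). Camera called these 5 lists higher with the preset correlation. For each of them the adjusted p was 0.195 with an estimated correlation.

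Other groups fell at 2 h. Of 10 aliphatic glucosinolate genes 9 fell and 1 rose (9 and 1 adjusted over the list alone), including the regulators MYB28 (-1.29) and MYB29 (-1.17) and CYP79F1 (-1.36), while SOT17 rose by 1.53. Camera's adjusted p was 0.0191, and the adjusted p = 0.523 with an estimated correlation. Low oxygen genes fell in 8 and rose in 1 of 13 cases (8 and 1 adjusted over the list alone), with SUS4 (-2.77) and HB1 (-2.65) beside PDC1 and SAD6 (adjusted p = 0.0398, and adjusted p = 0.523 with an estimated correlation). Clock genes fell in 11 and rose in 3 of 21 cases (the same when adjusted over the list alone), with PRR9 (-2.0), RVE8 (-1.74) and LHY (-1.60) beside CCA1, and as a list missed the threshold of limma's camera (adjusted p = 0.0519). The 9 other lists did not pass camera's threshold. Photosynthesis had 0 members higher and 3 lower of 35 (0 and 2 adjusted over the list alone), with LHCB2.1 at -1.42, and cell cycle 0 and 1 of 18 (0 and 0). Adjusted over the list alone, the counts were the same as over all genes for root markers (1 higher and 3 lower of 15), flavonoids (1 and 3 of 15) and auxin (11 and 5 of 22, with GH3.2 at 2.13). This held also for heat shock (2 and 0 of 9), senescence (4 and 2 of 9), AHL uptake and perception candidates (3 and 1 of 6) and reference genes (1 and 2 of 9). The 0 h and the flg22 arrays lay on different slides, and no mock-treated arrays at 2 h or 24 h were analysed. Effects of flg22, slide and elapsed time therefore share these contrasts.

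At 24 h of flg22 after acetone, FRK1 rose by 4.29 ± 0.21, PER4 by 7.34 ± 0.45 (2 arrays at 0 h above background), the defensin gene PDF1.2a by 3.04 ± 0.68 and the dark-inducible gene DIN1 by 2.46 ± 0.26. The anthocyanin gene DFR, which encodes dihydroflavonol reductase, fell (-5.42 ± 0.56), with 1 of the 3 arrays at 24 h above background. The root aquaporin gene TIP2;3 fell as well (limma adjusted p 2.7e-06). In all, 8192 genes passed in limma (3700 higher and 4492 lower), 1998 of them by at least 2-fold; without experiment 2 the count was 3915. Further large increases were those of CYP82C2 (at least 65.8-fold), NRT2.6 (at least 20.5-fold) and CYP82C3 (at least 14.7-fold). Others were those of the nitrate transporter gene NRT2.5 (at least 7.11-fold), the cytokinin oxidase gene CKX2 (at least 4.76-fold), PRX52 (6.32, 1 array at 0 h above background), PCR1 (4.48, 2 such arrays) and CYP71A12 (4.1). Further large decreases were those of UGT79B1 (at least 19.0-fold), LDOX, encoding the next enzyme after DFR (at least 5.25-fold), UMAMIT35 (at least 3.38-fold) and the ribonuclease gene RNS1 (-4.58). PRP1 (-3.93) and AGP30 (-3.67) fell too, as did LTP4 (-4.0), NDB4 (-3.97) and G3Pp2 (-3.41) with 1, 1 and 2 arrays at 24 h above background. The largest adjusted p among these genes was 0.0148, for LTP4 in limma.

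All 28 early flg22 response genes were higher at 24 h after acetone (28 adjusted over the list alone), with ZAT11 at 3.01, NHL10 at 2.74 and CYP81F2 at 2.47, and the list had a mean of 1.51. Camera gave adjusted p = 0.0348 with an estimated correlation, and 0.109 with the experiment as a block as well. Pattern receptor genes rose in 8 of 14 cases (9 adjusted over the list alone), with LYK4 (1.46) and BIK1 (1.25), while FLS2 had 0.49 and a limma adjusted p of 0.0783. Ethylene and defensin genes rose in 12 and fell in 1 of 18 cases (the same when adjusted over the list alone), with ACS7 (3.06), PDF1.2b (2.94) and ACS8 (at least 3.68-fold). Camalexin genes rose in 13 and fell in 2 of 18 (the same when adjusted over the list alone), with IGMT2 (1.79) and CYP71A13 (1.67). These 3 lists were called higher with the preset correlation, and each had an adjusted p = 0.0848 with an estimated correlation. Salicylic acid genes rose in 11 of 24 cases (12 adjusted over the list alone), with CBP60g (2.43), NIMIN1 (2.18), SARD1 (1.83) and ICS1 (0.65). PR1 had 2.13 with a limma adjusted p of 0.11, and the list's call was lost with an estimated correlation (adjusted p = 0.281). Phenylpropanoid genes rose in 15 and fell in 2 of 28 cases (18 and 4 adjusted over the list alone), with PRX71 (2.79), CAD5 (0.97) and PAL1 (0.86), while 4CL3 fell by 1.68 (adjusted p = 0.228 with an estimated correlation). Senescence and carbon starvation genes rose in 7 of 9 cases (7 adjusted over the list alone), with ASN1 (1.65) and SAG13 (1.36) beside DIN1 (adjusted p = 0.143 with an estimated correlation).

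Flavonoid and anthocyanin genes fell in 11 and rose in 1 of 15 cases at 24 h after acetone (12 and 1 adjusted over the list alone), with the regulator PAP1 at -2.95 (adjusted p = 0.162 with an estimated correlation). Root markers fell in 10 and rose in 1 of 15 cases (the same when adjusted over the list alone), with PRP3 (-2.82), the root hair expansin gene EXPA18 (-2.08) and the iron transporter gene IRT1 (-1.72) (adjusted p = 0.281 with an estimated correlation). Cell cycle genes fell in 4 of 18 cases (2 adjusted over the list alone), among them PCNA2 (-0.70) and MCM5 (-0.57) (adjusted p = 0.754 with an estimated correlation). Clock genes rose in 7 of 21 cases (7 adjusted over the list alone), with PRR5 (1.70) and RVE1 (1.29) (adjusted p = 0.210 with an estimated correlation). The 9 other lists did not pass camera's threshold at 24 h. Jasmonate genes were higher in 5 and lower in 6 of 28 cases (the same when adjusted over the list alone), with VSP1 at -1.80 and DOX1 at 1.38. Their median of -0.03 and mean of -0.05 had the opposite sign to camera's statistic. Detoxification genes were higher in 10 and lower in 7 of 40 cases (11 and 8 adjusted over the list alone), with GSTU10 at 2.41 and GSTU24 at -1.58, and their median of -0.20 and mean of 0.08 differed in sign. Of 9 heat shock genes 1 was higher and 4 were lower (2 and 4 adjusted over the list alone), with HSP70 at -1.61, a median of -0.09 and a mean of 0.03. Auxin genes were lower in 2 of 22 cases (2 adjusted over the list alone), of which LBD29 was not well above background in either group, and their median of 0.06 and mean of -0.06 differed in sign. Aliphatic glucosinolate genes had 0 higher and 2 lower of 10 (0 and 0 adjusted over the list alone), photosynthesis 1 and 2 of 35 (0 and 0) and low oxygen 1 and 0 of 13 (0 and 0). AHL candidates had 2 and 0 of 6 (the same adjusted over the list alone), and reference genes 0 and 1 of 9 (0 and 0).

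In seedlings pretreated with oxo-C14-HSL, at 2 h of flg22 FRK1 rose by 7.0 ± 0.21, WRKY22 by 4.65 ± 0.25, PROPEP3 by 6.71 ± 0.27, PER4 by 8.64 ± 0.45 and GLR2.9 by 7.4 ± 0.21 (1 array at 0 h above background). MYB111 (-4.97), GASA6 (-4.65) and CCA1 (-2.53) fell. In limma 13600 genes passed at 2 h (5848 higher and 7752 lower, 5191 by at least 2-fold). NRT2.6 rose at least 798-fold and PP2-B14 at least 48.4-fold. CYP82C3 rose by 7.76 and BGLU27 by 6.7 (1 array each at 0 h above background), PP2-B13 by 6.65 and the receptor-like kinase gene CRK31 by 6.42 (2 such arrays). Decreases were largest for ASG4 (-4.52), BBX31 (-4.47), CGA1 (-4.22), ABCF2 (-3.82, 2 arrays at 2 h above background) and BBX32 (-3.39). CHR34 (at least 3.26-fold), COR27 (at least 6.23-fold) and NCED9, which acts in abscisic acid synthesis (at least 4.06-fold), fell as well. The largest adjusted p among these genes in limma was 0.000112, for BBX32. Of the early flg22 response list 27 of 28 rose and 1 fell (the same when adjusted over the list alone; mean 3.28; adjusted p = 0.0136 with an estimated correlation). All 14 receptor genes rose (14 adjusted over the list alone; adjusted p = 0.0136 with an estimated correlation). Of 18 camalexin genes 16 rose and 1 fell (the same when adjusted over the list alone; adjusted p = 0.012 with an estimated correlation). Salicylic acid genes rose in 21 of 24 cases (21 adjusted over the list alone), with CBP60g at 3.97 and NIMIN1 at 3.80 (adjusted p = 0.181 with an estimated correlation). Aliphatic glucosinolate genes fell in 9 and rose in 1 of 10 cases (the same when adjusted over the list alone), with MYB29 at -2.02 and MYB28 at -1.73 (adjusted p = 0.438 with an estimated correlation). The jasmonate, ethylene, phenylpropanoid and detoxification lists also passed as higher with the preset correlation, and the low oxygen and clock lists as lower. Their adjusted p lay between 0.163 and 0.511 with an estimated correlation.

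At 24 h after oxo-C14-HSL, FRK1 had risen by 4.71 ± 0.21, PER4 by 6.88 ± 0.45, CYP82C2 by 5.37 ± 0.45 and PRX52 by 5.25 ± 0.72. DFR had fallen (-5.42 ± 0.56, 1 array at 24 h above background). In limma 9165 genes passed (4015 higher and 5150 lower, 2158 by at least 2-fold). With only the 6 compared arrays in the fit the count was 6052, and without experiment 2 it was 5120. Other large increases were those of NRT2.6 (at least 16.4-fold), CKX2 (at least 6.1-fold), ACS8 (at least 4.77-fold), CYP82C3 (4.54, 1 array at 0 h above background), PCR1 (5.22, 2 such arrays) and the phloem protein gene PP2-A7 (3.9). Other large decreases were those of CYP82C4 (at least 11.9-fold), LTP4 (at least 12.4-fold), UMAMIT35 (at least 4.72-fold), CHR34 (at least 3.4-fold), AGP30 (-4.67) and CORI3 (-3.22). UGT79B1 (-4.5), NDB4 (-4.73) and LDOX (-4.38) fell too, with 1 array each at 24 h above background. All 28 early flg22 response genes were higher (28 adjusted over the list alone; mean 1.76; adjusted p = 0.0166 with an estimated correlation, and 0.057 with the experiment as a block as well). Cell cycle genes fell in 15 of 18 cases (16 adjusted over the list alone), with PCNA2 at -0.90 and the cytokinesis gene KNOLLE at -0.85 (adjusted p = 0.356 with an estimated correlation). Photosynthesis genes passed camera's preset test as lower (adjusted p = 0.018), with 2 of 35 lower in limma and 0 adjusted over the list alone (adjusted p = 0.735 with an estimated correlation). Their mean of -0.22 was above 0 after quantile normalization (0.0133). PDF1.2a had 1.58 (limma adjusted p 0.0781) and PR1 had 0.34 (0.808). In total 12 lists passed with the preset correlation, and the early response list alone with an estimated one. Jasmonate genes did not pass, with a median of -0.08, a mean of -0.02 and a camera statistic above 0.

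**Figure D2:**
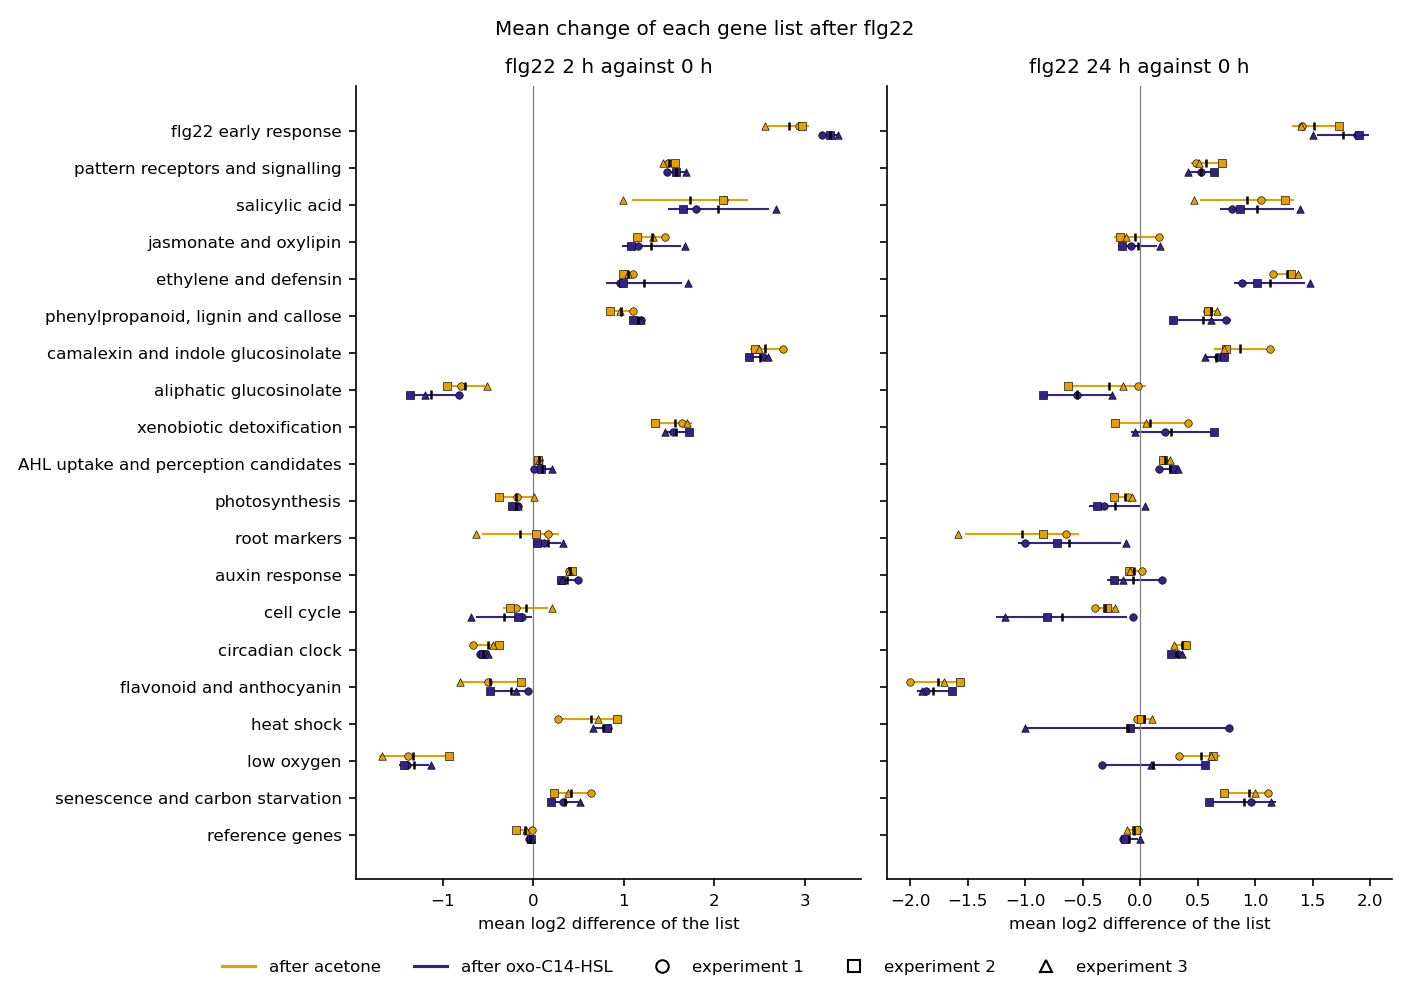
Mean log2 difference of each of the 20 gene lists at 2 h (left) and 24 h (right) of flg22 from 0 h, after acetone and after oxo-C14-HSL; points are the 3 experiments, ticks their mean and lines ± 1 SD. The early response list had means of 2.82 and 3.28 at 2 h and of 1.51 and 1.76 at 24 h.

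The arrays at 2 h and 24 h of flg22 shared slides. Between these times after acetone the terpene synthase gene TPS04 (-6.30 ± 0.76, 1 array at 24 h above background), WRKY30 (-4.97 ± 0.25), CYP81F2 (-2.94 ± 0.27) and FRK1 (-1.54 ± 0.21) fell. MYB111 rose by 4.34 ± 0.33, CCA1 by 2.54 ± 0.14, PDC1 by 3.70 ± 0.51 and PR1 by 2.83 ± 0.99 (limma adjusted p 0.0263). In limma 11320 genes passed (5832 higher and 5488 lower, 3359 by at least 2-fold). Among other large decreases were FAMT (-6.05), the tyrosine aminotransferase gene TAT3 (-5.88), TDR1 (-5.57) and DFR (-5.25, 1 array at 24 h above background). Further ones were CRK39 (at least 11.1-fold), IGMT3 (-4.49), BGLU27 (-4.48) and AGP30 (-4.40). Among other large increases were ARD3 (4.98), GRP19 (4.85, 1 array at 2 h above background), GASA6 (4.25), CGA1 (4.24) and SAD6 (3.92). LAS1 (3.78), ASG4 (3.76), LURE1.1 (at least 8.01-fold) and the cold-regulated gene COR27 (at least 5.86-fold) rose too. Of the early flg22 response list 23 of 28 fell and 2 rose (24 and 2 adjusted over the list alone; adjusted p = 0.0784 with an estimated correlation). Of the camalexin list 15 of 18 fell and 2 rose (the same when adjusted over the list alone), with IGMT2 at -4.26 and PAD3 at -3.21. Its adjusted p was 0.0222 with an estimated correlation, and 0.0894 with the experiment as a block as well. Detoxification genes fell in 28 and rose in 2 of 40 cases (30 and 2 adjusted over the list alone; adjusted p = 0.212 with an estimated correlation). Jasmonate genes fell in 17 and rose in 5 of 28 cases (the same when adjusted over the list alone), with JAZ8 at -4.37 (1 array at 24 h above background) and AOC2 at -4.03. Their adjusted p was 0.212 with an estimated correlation. Clock genes rose in 12 and fell in 1 of 21 cases (14 and 1 adjusted over the list alone; adjusted p = 0.0711 with an estimated correlation). The ethylene and defensin list had 8 members higher, with PDF1.2b at 2.79, and 7 lower, with ORA59 at -2.63 (the same when adjusted over the list alone). Its median of 0.20 and mean of 0.23 had the opposite sign to the statistic of limma's camera (adjusted p = 0.76). Aliphatic glucosinolate genes, of which 7 of 10 rose and 1 fell (the same when adjusted over the list alone), passed camera's preset test only with the experiment as a block (adjusted p 0.0521 without and 0.027 with it).

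After oxo-C14-HSL the same interval gave 12326 genes past the threshold in limma (6272 higher and 6054 lower, 3718 by at least 2-fold). TPS04 (-6.09 ± 0.76, 2 arrays at 24 h above background), WRKY30 (-5.43 ± 0.25) and FRK1 (-2.29 ± 0.21) fell, and MYB111 rose by 4.72 ± 0.33 and CCA1 by 2.74 ± 0.14. Camalexin genes fell in 16 of 18 cases and rose in 2 (the same when adjusted over the list alone). Their adjusted p was 0.0229 with an estimated correlation, and 0.0973 with the experiment as a block as well. With the preset correlation 13 lists passed, of which this was the one that passed with an estimated correlation. TAT3 (-5.87), FAMT (-5.68), NRT2.6 (-5.6), DFR (-5.57, 1 array at 24 h above background) and BGLU27 (-5.33) were among the genes that fell most. TDR1 (-5.3), GAD4 (-4.92) and ERF14 (-4.77, 1 such array) followed. GASA6 (4.71), CGA1 (4.46), ARD3 (4.26), BBX31 (4.14), ASG4 (4.09), EXPA8 (3.52), CYP89A9 (3.48), BBX32 (3.44) and COR27 (at least 8.64-fold) rose most.

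The responses at 2 h and 24 h overlapped. After acetone 2421 genes were higher at both times and 2378 lower at both, where independent lists of these sizes would share 764 and 1261. Opposite calls were made for 504 genes, and the log2 differences correlated with r = 0.656 across genes. Both times share the 0 h arrays, and unchanged groups simulated against shared controls gave r = 0.501 and a covariance of 0.0308, against an observed covariance of 0.516. After oxo-C14-HSL the shared numbers were 2706 (independent 912) and 2773 (independent 1551), with r = 0.671 and a covariance of 0.558. With 3 control arrays no split left 2 in each part, so some of the excess may come from them. Between pretreatments, which share no arrays but the same slides and experiments, the 2 h responses correlated with r = 0.957 and the 24 h responses with r = 0.915. At 2 h 4790 genes were higher and 6358 lower under both (independent lists 1207 and 2176), and at 24 h 3052 and 3727 (independent lists 577 and 899).

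**Figure D3:**
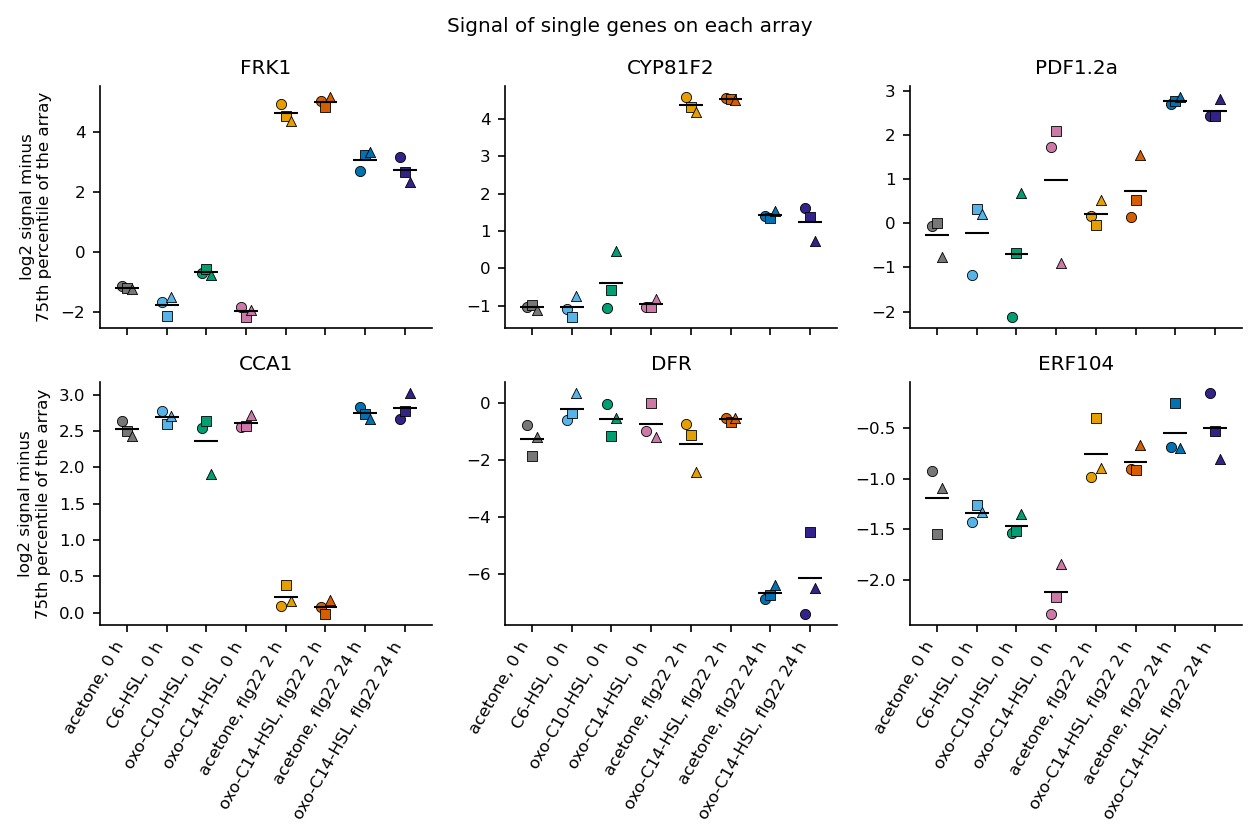
log2 signal of FRK1, CYP81F2, PDF1.2a, CCA1, DFR and ERF104 minus the array's 75th percentile, for the 8 groups; each point is 1 array, shaped by experiment, and each line is the mean of 3 arrays. FRK1 stands 5.82 higher at 2 h of flg22 than at 0 h after acetone, and DFR differs by -5.42 at 24 h.

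C6-HSL, the unsubstituted AHL with the shortest chain, gave no gene past the threshold against acetone at 0 h, with or without the experiment as a block. In limma 0 of 25740 genes passed, with 374 at an unadjusted p under 0.05, and the 95% interval of the difference lay within 2-fold either way for 85.0% of genes. The 5 named genes with the smallest p were NAC061 (1.80 ± 0.42), GulLO5 (-0.75), ABCG37 (-0.48), MLS (-0.84) and CRK37 (1.38), all with a limma adjusted p of 1.0. PR1 had 1.78, the anthocyanin gene DFR 1.06 and FRK1 -0.57, none of which passed. Of the 20 lists 9 passed camera's preset test. Those described here and for the other AHL contrasts are, of the lists called, the 3 with the largest absolute means, a choice made after the values were seen. Flavonoid genes had a mean of 0.33, with LDOX at 0.91 (-0.04, 0.52 and 0.52 in experiments 1 to 3; adjusted p = 0.486 with an estimated correlation). Salicylic acid genes had 0.32 (0.85, -0.08 and 0.20; adjusted p = 0.492 with an estimated correlation). Cell cycle genes had -0.28, with CYCA1;1 at -0.39 (-0.39, -0.35 and -0.09; adjusted p = 0.486 with an estimated correlation). The preset call of flavonoids ended without the C6-HSL array of experiment 3 (mean 0.20, adjusted p 0.0636; 0.19 without the acetone array of experiment 2), and that of salicylic acid without the acetone array of experiment 1 (0.17, 0.098; 0.21 and 0.52 without the C6-HSL array of experiment 1 or 2). No member of any list passed when adjusted over the list alone.

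oxo-C10-HSL also gave 0 genes past the threshold in limma, but 1834 had an unadjusted p under 0.05. That number was 639 without the oxo-C10-HSL array of experiment 3, and 3188 or 3337 without that of experiment 1 or 2. The smallest p among named genes belonged to the peptide transporter gene PTR3 (0.87 ± 0.17, adjusted p 0.295), GulLO5 (-1.03, 0.295), the root growth peptide gene RGF7 (0.92, 0.465), CYP71B3 (0.69) and SAUR36 (0.34). The 95% interval lay within 2-fold for 82.0% of genes. Camera's preset test called 8 lists, of which low oxygen had the largest mean (0.64, with LBD41 at 1.48 and PCO2 at 1.36), followed by root markers (-0.43, EXPA7 at -0.63) and flavonoids (-0.31, MYB12 at -1.53). Their adjusted p were 0.455, 0.455 and 0.701 with an estimated correlation. The experiments differed in sign: low oxygen had -0.15, 0.60 and 1.46, root markers 0.11, -0.31 and -1.09, and flavonoids 0.01, 0.13 and -1.07. Without the oxo-C10-HSL array of experiment 3 low oxygen had 0.28 and flavonoids 0.03 (preset adjusted p 0.447; mean -0.57 without that of experiment 1). Root markers had -0.23 without the acetone array of experiment 3 and no call without experiment 3 (0.217), and flavonoids lost the call without the acetone array of experiment 1 (0.0878) or 3 (0.0742). Adjusted over the list alone, 4 early response genes (1 higher and 3 lower), 1 receptor gene, 1 AHL candidate and 1 flavonoid gene passed.

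oxo-C14-HSL, with the longest chain, gave 0 genes past the threshold in limma and 377 at an unadjusted p under 0.05; the 95% interval lay within 2-fold for 84.9% of genes. The named genes with the smallest p were the kinase gene MKK9 (-0.61 ± 0.10, adjusted p 0.101), TEM1 (-0.92 ± 0.16, 0.113), ERF105 (-0.95 ± 0.17, 0.152), RAV2 (-0.57, 0.29) and ERF104 (-0.93, 0.402), each with a negative difference in all 3 experiments. The early flg22 response list, to which ERF104 and ERF105 belong, had a mean of -0.29 (median -0.20), with ZAT10 at -0.86 and FRK1 at -0.78. It was lower in each experiment. Camera's preset test gave it an adjusted p of 2.7e-15, and the adjusted p = 0.0871 with an estimated correlation. Of its 28 members 7 passed as lower when adjusted over the list alone, against 0 over all genes. Low oxygen (mean 0.33) and aliphatic glucosinolates (0.17) were the others with the largest means among the 7 lists past the preset test, with adjusted p = 0.603 and 0.696 with an estimated correlation. The salicylic acid list was called lower with the preset correlation (adjusted p 0.0268) and not with the experiment as a block (0.0729) or an estimated correlation (adjusted p = 0.824). It had 0.41, 0.31 and -0.99 by experiment, and was called higher without experiment 3 (0.36, 0.00105). It was not called without the oxo-C14-HSL (0.22, 0.323) or acetone (0.05, 0.97) array of experiment 3 or the acetone array of experiment 2 (0.113), and had -0.24, -0.19 and -0.30 without the acetone or oxo-C14-HSL array of experiment 1 or the oxo-C14-HSL array of experiment 2. Low oxygen lost the call without the oxo-C14-HSL array of experiment 1 (0.0915) or the acetone array of experiment 2 (0.113), and had 0.51 without the acetone array of experiment 1. Aliphatic glucosinolates lost it without the acetone array of experiment 1 (0.659) or 3 (0.116) or the oxo-C14-HSL array of experiment 2 (0.755), and had 0.29 and 0.36 without the oxo-C14-HSL array of experiment 1 or the acetone array of experiment 2. For ethylene and defensin genes the median of -0.10 and the mean of 0.11 differed in sign, as did those of the flavonoid list (-0.06 and 0.01).

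**Figure D4:**
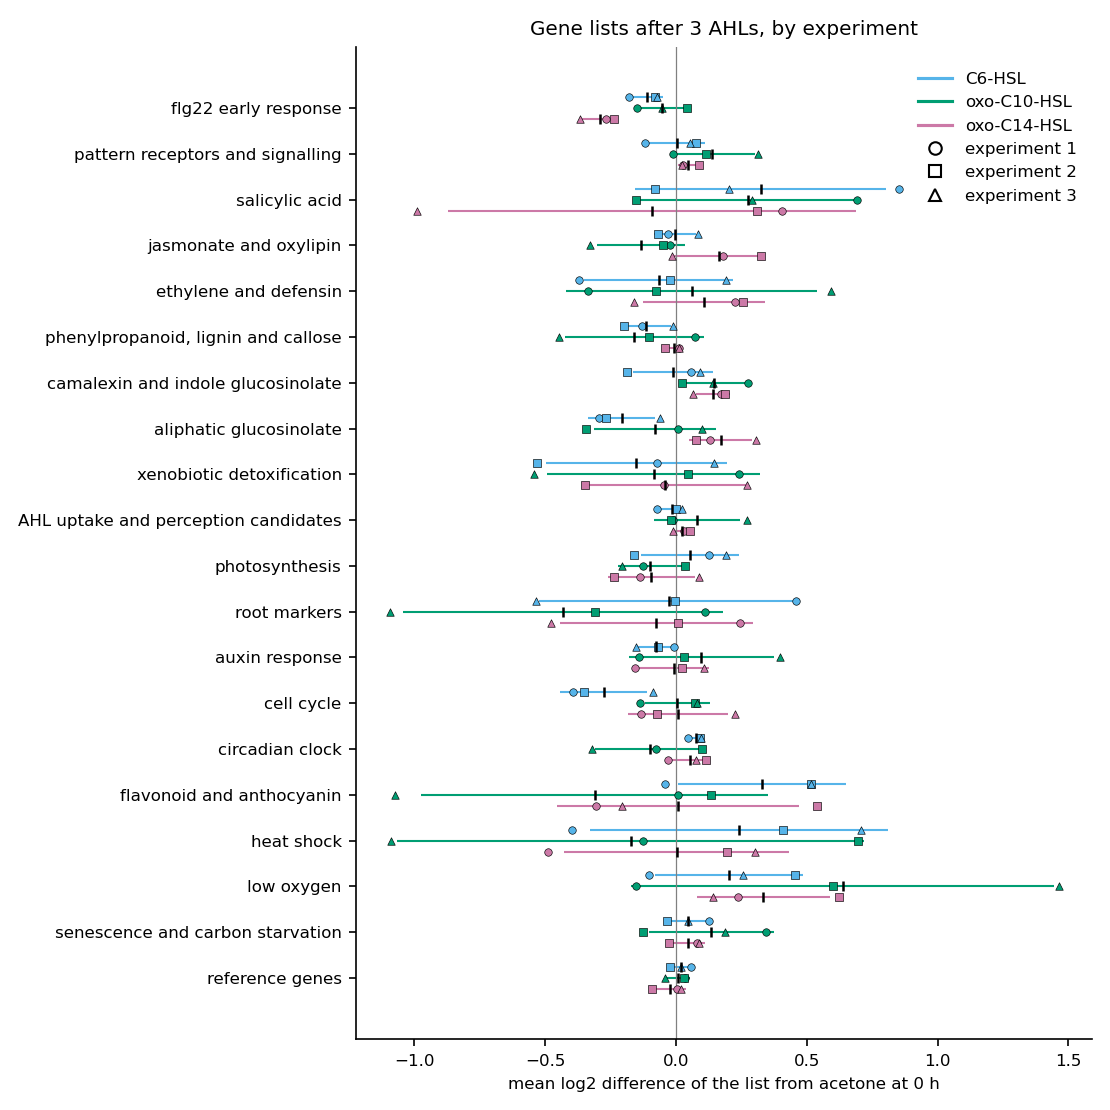
Mean log2 difference of each of the 20 gene lists from acetone at 0 h for C6-HSL, oxo-C10-HSL and oxo-C14-HSL; points are the 3 experiments, ticks their mean and lines ± 1 SD. The early flg22 response list was lower in all 3 experiments after oxo-C14-HSL (mean -0.29), and low oxygen genes after oxo-C10-HSL ranged from -0.15 to 1.46.

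Compared with each other at the same dose and time, the AHLs differed in very few genes. Between oxo-C10-HSL and C6-HSL, which differ by the 3-oxo group and 4 carbons of the chain, RGF7 was higher after oxo-C10-HSL by 1.35 (95% interval 0.96 to 1.75, limma adjusted p 0.0254). The unnamed locus AT5G39580, given here only because the count was so small, was higher by 1.1 (adjusted p 0.0254). These were the 2 genes past the threshold, with 2036 at an unadjusted p under 0.05. RGF7 passed with the experiment as a block (0.0335), but not with slide as a fixed block (0.0714) or only the arrays compared (0.969), where 0 genes passed. It missed the threshold without the C6-HSL array of experiment 1, 2 or 3 (0.122, 0.17 and 0.067; 0 genes) or the oxo-C10-HSL array of experiment 1 or 2 (0.0529 and 0.0794; 2 and 1 other genes). AT5G39580 passed in none of the fits without 1 array. FRK1 had 1.09 (0.65 to 1.53) and did not pass (limma adjusted p 0.128). Between oxo-C14-HSL and oxo-C10-HSL, which differ by 4 carbons, 0 genes passed in limma (1608 at an unadjusted p under 0.05). FRK1 had -1.30 (-1.74 to -0.86), PTR3 -0.95 (-1.29 to -0.60) and RGF7 -1.08 (-1.47 to -0.68), each with a limma adjusted p of 0.0966. With the experiment as a block 6 genes passed, among them FRK1 and PTR3 (adjusted p 0.0494 each), neither of which passed with slide as a fixed block (0.087 and 0.0793), although slide and experiment coincide for these arrays. Between oxo-C10-HSL and C6-HSL PTR3 had 1.0 (limma adjusted p 0.0854, and 0.0335 and 0.076 with these blocks). Between oxo-C14-HSL and C6-HSL 0 genes passed in limma (811 at an unadjusted p under 0.05), with CYP82C2 at 2.38 (1.43 to 3.32), SKOR at 0.77 and GolS4 at 1.09, each at a limma adjusted p of 0.266. The 95% interval of the difference lay within 2-fold for 81.3% of genes for oxo-C10-HSL against C6-HSL, 81.7% for oxo-C14-HSL against oxo-C10-HSL and 83.8% for oxo-C14-HSL against C6-HSL, so larger differences in the other genes were not excluded.

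Camera's preset test called 10 of the 20 lists between oxo-C10-HSL and C6-HSL, 5 between oxo-C14-HSL and oxo-C10-HSL and 8 between oxo-C14-HSL and C6-HSL, and none with an estimated correlation. Between oxo-C10-HSL and C6-HSL the means were largest for flavonoids (-0.64), low oxygen (0.43) and heat shock (-0.41), with adjusted p = 0.401, 0.494 and 0.525 with an estimated correlation. By experiment they were 0.05, -0.38 and -1.59 for flavonoids, -0.05, 0.15 and 1.21 for low oxygen, and 0.27, 0.29 and -1.80 for heat shock. Without the oxo-C10-HSL array of experiment 3 they were -0.30, 0.08 and 0.13, the last 2 no longer called (preset adjusted p 0.631 and 0.62; flavonoids lost the call without experiment 3, mean -0.17, 0.0829), and heat shock had -0.27 (0.201) without the C6-HSL array of experiment 3 and -0.72 and -0.65 without the oxo-C10-HSL array of experiment 1 or 2. Heat shock and the receptor list lost the preset call with the experiment as a block (both 0.0575). Salicylic acid genes (-0.37), root markers (0.36) and jasmonate genes (0.30) had the largest means of those called between oxo-C14-HSL and oxo-C10-HSL (adjusted p = 0.558, 0.505 and 0.505 with an estimated correlation). Salicylic acid genes had -0.29, 0.46 and -1.28 by experiment, -0.06 without the oxo-C14-HSL array of experiment 3 (preset adjusted p 0.138), -0.22 without the oxo-C10-HSL array of experiment 3, and -0.57 and -0.58 without the oxo-C10-HSL or oxo-C14-HSL array of experiment 2. Without the oxo-C10-HSL array of experiment 3 root markers had 0.22 and jasmonate genes 0.19, and the latter 0.17 without the oxo-C14-HSL array of experiment 2. Between oxo-C14-HSL and C6-HSL they were salicylic acid (-0.42), aliphatic glucosinolates (0.38) and flavonoids (-0.32) (adjusted p = 0.27 each with an estimated correlation). Salicylic acid genes had -0.45, 0.39 and -1.19 by experiment, -0.11 and -0.63 without the oxo-C14-HSL array of experiment 3 or 2, and no call without experiment 3 (0.165). Aliphatic glucosinolates had 0.23 without the C6-HSL array of experiment 1 and 0.24 without the oxo-C14-HSL array of experiment 2, and flavonoids (-0.27, 0.03 and -0.72 by experiment) -0.19 without the C6-HSL array of experiment 3. The log2 differences of the 3 AHLs from the shared acetone arrays correlated across genes with r = 0.386 for C6-HSL and oxo-C10-HSL, 0.401 for C6-HSL and oxo-C14-HSL, and 0.410 for oxo-C10-HSL and oxo-C14-HSL. Unchanged groups simulated against shared controls gave r = 0.501 (SD 0.013 over 100 simulations), and the observed covariances of 0.0232, 0.0179 and 0.0245 lay below the simulated 0.0308. The simulation used the spread of the fit with the experiment as a block, pooled over groups, and left out the slide that the 0 h arrays of an experiment shared.

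With flg22, oxo-C14-HSL against acetone pretreatment gave 0 genes past the threshold in limma at 2 h (1290 at an unadjusted p under 0.05) and 0 at 24 h (1249), and the 95% interval lay within 2-fold for 83.6% and 82.8% of genes. At 2 h the named genes with the smallest p were the auxin synthesis gene TAR2 (-0.49 ± 0.10), the osmotin gene OSM34 (0.89 ± 0.19), NAC047 (0.48) and the lignin pathway gene C4H (0.33), each at a limma adjusted p of 0.947, and TRM24 (-0.78, 0.967). FRK1 had 0.39, WRKY22 0.47 and the alcohol dehydrogenase gene ADH1 1.22. At 24 h they were RABH1d (1.64 ± 0.31), the potassium channel gene GORK (0.50), bZIP58 (0.58), MLP34 (0.74) and ROPGEF10 (1.38), at adjusted p of 0.997, and FRK1 had -0.36. Camera's preset test called 12 lists at 2 h, with low oxygen (mean 0.34), ethylene and defensin (0.28) and flavonoids (0.25) the largest, each with adjusted p = 0.508 with an estimated correlation. By experiment they were 0.22, 0.12 and 0.68, 0.08, 0.26 and 0.50, and 0.13, 0.20 and 0.41. Low oxygen had 0.11 without the acetone array of experiment 3 and no call without experiment 3 (0.171). The ethylene call ended without the acetone array of experiment 2 (0.0815) or the oxo-C14-HSL array of experiment 3 (0.149), and the flavonoid call without the acetone array of experiment 1 (0.0813; mean 0.34) or 3 (0.0555; 0.13), the oxo-C14-HSL array of experiment 3 (0.108), or with the experiment as a block (0.0502). At 24 h it called 5 lists, with cell cycle (-0.37; 0.20, -0.59 and -0.73 by experiment), root markers (0.34; -0.11, 0.13 and 0.99) and jasmonate (0.19) the largest, each with adjusted p = 0.496 with an estimated correlation. Without the oxo-C14-HSL array of experiment 3 cell cycle had -0.17 and root markers 0.09 (no longer called, 0.209), and without that of experiment 1 cell cycle had -0.62. Adjusted over the list alone, 1 phenylpropanoid gene and 2 low oxygen genes passed at 2 h and 0 at 24 h.

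The difference between the flg22 responses of oxo-C14-HSL and acetone seedlings, tested as an interaction, gave 0 genes in limma at 2 h (784 at an unadjusted p under 0.05) and 0 at 24 h (460). The 95% interval of this difference lay within 2-fold for 73.2% and 73.3% of genes. At 2 h the smallest p were those of NAC047 (0.89 ± 0.15, limma adjusted p 0.494), TEM1 (0.96), RAV2 (0.66), FRK1 (1.18 ± 0.30) and MKK9 (0.53), and at 24 h those of MKK9 (0.70 ± 0.14, 0.814), NAC047 (0.69), TEM1 (0.99), RABH1d (1.75) and RAV1 (0.77). MKK9, TEM1, RAV2 and FRK1 had negative differences between oxo-C14-HSL and acetone at 0 h, which enter the interaction with the opposite sign. Camera's preset test called 8 lists at each time and none with an estimated correlation. For the early flg22 response list the mean was 0.46 at 2 h, with ZAT10 at 0.97 and WRKY40 at 0.87 (5 of 28 members higher when adjusted over the list alone, 0 over all genes; adjusted p = 0.103 with an estimated correlation), and 0.25 at 24 h (adjusted p = 0.434 with an estimated correlation).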

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

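The tests of slides, time of day, single arrays, scaling and root share were chosen only after the result was seen, and the splits of the arrays before.

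After 2 h of flg22, 12539 of 25740 genes passed after acetone and 13600 after oxo-C14-HSL, and in each experiment the arrays with flg22 lay on another slide than those without. A difference between slides as the whole cause was argued against by changes within slides, where 12635 genes passed between 24 h and 2 h after acetone and 13894 after oxo-C14-HSL with slide as a fixed block. Of the genes past the threshold at 2 h, 65.1% after acetone (8159) and 65.8% after oxo-C14-HSL (8954) changed in the opposite direction there, although the 2 h arrays enter both comparisons and slides could still account for part of each count. Time of day in place of flg22 stayed open, because seedlings without flg22 at 2 h and 24 h were not analysed here: 14 of 21 clock genes passed at 2 h after acetone (66.7%, against 48.7% of all genes; two-sided Fisher's exact test, p 0.126) and 7 at 24 h. The response to flg22 that the design names stayed open with it and could not be separated from elapsed time in these arrays.

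At 0 h the early flg22 response list had a mean log2 difference of -0.289 between oxo-C14-HSL and acetone (-0.27, -0.24 and -0.37 by experiment), past limma's camera with the preset correlation (adjusted p 2.7e-15) and not with an estimated correlation (adjusted p = 0.0871, and 0.257 with the experiment as a block as well). A single array or experiment as the cause was argued against by the fits without each of them, in which the mean nearest to 0 was -0.251 (without experiment 3), and scaling between arrays by the mean of -0.275 after quantile normalization. The 10 splits of the 6 arrays were too few for a share under 0.05; 1 of 10, the real one, reached a mean of 0.289 in size, the highest other was 0.217, and the highest of the 3 others that parted all 3 pairs was 0.132, while the other 6 splits parted 1 pair and kept the arrays of 2 experiments together. An effect of oxo-C14-HSL may underlie the difference, but it cannot be told apart from the position on the slide, which was fixed for each group.

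More genes had an unadjusted p under 0.05 after oxo-C10-HSL (1834) than after C6-HSL (374) or oxo-C14-HSL (377), with 0 past the threshold in limma for each. A single oxo-C10-HSL array is a candidate cause: the count was 639 without the array of experiment 3 and 493 without that experiment, against 1094 without the acetone array of experiment 3, and 3188 and 3337 without the oxo-C10-HSL arrays of experiments 1 and 2. A lower share of root tissue would lower root markers and raise photosynthesis genes. Root markers had a mean of -0.430 (0.11, -0.31 and -1.09 by experiment) and photosynthesis genes -0.0987 (-0.13, 0.04 and -0.21). This stayed open, since photosynthesis went both ways, and so did an effect of oxo-C10-HSL itself, as named by the design.

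For comparisons of 3 against 3 arrays, the 10 splits were too few for a share under 0.05. The real count was reached by 1 of 10 splits in the flg22 comparisons: 12539 at 2 h after acetone (highest other 0), 8192 at 24 h (1), 13600 and 9165 after oxo-C14-HSL (0 and 1), and 11320 and 12326 between 24 h and 2 h (1 and 292). Among the 4 splits that parted all 3 pairs, the highest other was 0 in each of these. The split with 292 genes kept the arrays of experiments 1 and 3 together and set these experiments against each other, which points to a structure of the samples. The same split of the oxo-C14-HSL and acetone arrays at 24 h gave 11 genes, against 0 for the real one. oxo-C10-HSL against C6-HSL gave 2 genes in 1 of 10 splits (highest other 1, and 0 among those parting all 3 pairs). Where the real count was 0, every split reaches it by construction, so these splits say nothing about chance. This holds for the other AHL comparisons, with 10 of 10: the highest other was 0 for C6-HSL against acetone, for oxo-C14-HSL against acetone at 2 h and against C6-HSL, 1 for oxo-C10-HSL against acetone and for oxo-C14-HSL against oxo-C10-HSL, and 3 for oxo-C14-HSL against acetone at 0 h, the last 3 in splits parting all 3 pairs, and for oxo-C10-HSL against acetone also in 1 that parted 1 pair. It holds as well for the interactions at 2 h and 24 h, with 100 of 100 splits drawn (highest other 1, and 0 among the 14 that parted as many pairs). At an unadjusted p under 0.05 the comparisons with 0 had 1.45% (C6-HSL against acetone) to 7.13% (oxo-C10-HSL against acetone) of genes.

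Of the 20 lists, 8 at each time drew attention in camera's preset test of the interaction, which differences at 0 h enter with the opposite sign. None passed with an estimated correlation, and the call of 14 of these 16 ended in at least 1 of the 15 fits without an array or experiment. Arrays left out are written as time, pretreatment and experiment. At 2 h the early response list had a mean of 0.458 (0.25, 0.32 and 0.81 by experiment; adjusted p 1.4e-14, and adjusted p = 0.103 with an estimated correlation) and kept the call in these fits, with a mean of 0.28 without experiment 3. Phenylpropanoid genes had 0.187 (0.08, 0.25 and 0.23; 0.000394) and kept it too, with a mean of 0.12 without 0 h acetone 2. For these genes and each of the following 2 h lists the adjusted p was 0.685 with an estimated correlation. Salicylic acid genes had 0.311 (-0.31, -0.45 and 1.69; 0.000803), with -0.380 without experiment 3 (adjusted p 0.0459 in the other direction), no call without 0 h acetone 3 (0.0552) or 0 h oxo-C14-HSL 3 (0.274), and means of 0.50, 0.08 and 0.52 without 2 h acetone 2, 2 h acetone 3 and 0 h oxo-C14-HSL 2. Ethylene and defensin genes had 0.173 (-0.14, 0.00 and 0.66; 0.0285, and 0.0595 with the experiment as a block), with no call without 0 h acetone 1 (0.0652) or 2 (0.077), 2 h acetone 2 (0.0716), 0 h (0.412) or 2 h (0.148) oxo-C14-HSL 3, or experiment 3 (0.821), and a mean of 0.27 without 0 h oxo-C14-HSL 1. Aliphatic glucosinolate genes had -0.368 (-0.02, -0.40 and -0.68; 0.000677), with no call without 0 h acetone 1 (0.0652), 0 h oxo-C14-HSL 2 (0.0542) or experiment 3 (0.0692), and a mean of -0.55 without 0 h acetone 2. Root markers had 0.304 (-0.05, 0.01 and 0.95; 0.0261, and 0.055 with the block), with no call without 2 h acetone 1 (0.0876), 0 h acetone 3 (0.538), 2 h oxo-C14-HSL 3 (0.186) or experiment 3 (mean -0.0213). Cell cycle genes had -0.243 (0.06, 0.10 and -0.89; 0.000756), with no call without 2 h oxo-C14-HSL 3 (0.115) or experiment 3 (mean 0.0785). Flavonoid genes had 0.24 (0.44, -0.34 and 0.62; 0.0285, and 0.0888 with the block), with no call without experiment 1 (0.382) or 3 (0.17), nor without 7 single arrays: 0 h acetone 1 (0.112) or 3 (0.121), 0 h oxo-C14-HSL 1 (0.199) or 3 (0.0918), 2 h acetone 1 (0.0857) or 3 (0.0547), and 2 h oxo-C14-HSL 3 (0.111). Their means were 0.38 and 0.36 without 0 h acetone 2 and 0 h oxo-C14-HSL 2.

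At 24 h the early response list had 0.254 (0.48, 0.17 and 0.11 by experiment; limma camera adjusted p 1.5e-07), 0.140 without experiment 1 (0.0862), and 0.16 and 0.39 without 24 h oxo-C14-HSL 1 and 3. Camalexin and indole glucosinolate genes had -0.211 (-0.45, -0.02 and -0.17; 0.00925), with no call without 0 h acetone 1 (0.306), 24 h acetone 1 (0.176), 24 h oxo-C14-HSL 1 (0.176) or 3 (0.103), 0 h oxo-C14-HSL 2 (0.151) or experiment 1 (0.849). Root markers had 0.412 (-0.35, 0.12 and 1.47; 2.4e-05), with no call without 24 h oxo-C14-HSL 3 (0.0673) or experiment 3 (mean -0.115), and a mean of 0.21 without 0 h acetone 3. Cell cycle genes had -0.382 (0.33, -0.52 and -0.96; 8.7e-09), with no call without experiment 3 (-0.0937; 0.471), and means of -0.63 and -0.17 without 24 h oxo-C14-HSL 1 and 3. These 4 lists had adjusted p = 0.434 with an estimated correlation. The early response list was no higher on average at 24 h (array means 0.93, 0.82 and 0.48, against 0.72, 0.89 and 0.74 after acetone). Its 24 h value thus rests on a lower 0 h level after oxo-C14-HSL. Salicylic acid genes had 0.0926 (-0.26, -0.39 and 0.92; 0.031, and 0.0511 with the block; adjusted p = 0.845 with an estimated correlation), with no call without 24 h acetone 1 (0.539) or 3 (0.113), 0 h acetone 2 (0.0742) or 3 (0.561), 24 h oxo-C14-HSL 2 (0.825), 0 h oxo-C14-HSL 3 (0.852) or experiment 3 (mean -0.321). Their means were 0.24, 0.27, 0.19, 0.30 and 0.21 without 0 h acetone 1, 24 h acetone 2, 0 h oxo-C14-HSL 1 and 2, and 24 h oxo-C14-HSL 3. Aliphatic glucosinolate genes had -0.278 (-0.53, -0.22 and -0.09; 0.00155; adjusted p = 0.711 with an estimated correlation), with no call without 0 h acetone 1 (0.272), 24 h oxo-C14-HSL 1 (0.329), 0 h oxo-C14-HSL 2 (0.188) or experiment 1 (0.452), and a mean of -0.46 without 0 h acetone 2. Detoxification genes had 0.189 (-0.20, 0.86 and -0.10; 0.00128; adjusted p = 0.711 with an estimated correlation), with no call without 24 h oxo-C14-HSL 2 (0.129) or experiment 2 (mean -0.149). Their means were 0.36, 0.10 and 0.11 without 24 h acetone 1, 2 and 3, and 0.09 and 0.29 without 0 h oxo-C14-HSL 2 and 3. Low oxygen genes had -0.416 (-0.67, -0.07 and -0.51; 0.0123; adjusted p = 0.711 with an estimated correlation), with no call without 0 h oxo-C14-HSL 1 (0.135), 24 h acetone 1 (0.0639) or 3 (0.069), 24 h oxo-C14-HSL 1 (0.329) or 3 (0.104), 0 h acetone 2 (0.134) or experiment 1 (0.452), and a mean of -0.66 without 24 h oxo-C14-HSL 2.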

How the results depend on the processing

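Of the tests here, only normexp was chosen after the result was seen. Only genes and lists named in the text were rechecked, and no gene past the threshold changed direction. Apart from leave-outs, 3790 gene values kept their side, 15 lost the call and 14 gained one. For lists the numbers were 1098, 122 and 14, with 9 reversed. Leave-outs gave 2858, 44 and 2 for genes, and 1016, 112 and 17 for lists, with 13 reversed. Of the list calls lost, 80 went with an estimated correlation. Of the correlations between comparisons 39 moved by less than the spread and 10 by more, and in leave-outs 20 and 16. Camera was not rerun with slide as a random block or with trend and robust. Fits without 1 array or experiment left groups of 2, assumed to vary like the others. Signal over background limited the values of dim genes: 22092 genes were well above background on all 24 arrays, and without a filter 34291 genes were tested.

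With a 2-fold limit added, which can only lower a count, the flg22 counts were 4398 (2 h) and 1998 (24 h) after acetone, 5191 and 2158 after oxo-C14-HSL, and 3359 and 3718 between 24 h and 2 h. Under the other alternatives the 6 counts stayed within 1.5 times, except 6052 for 24 h after oxo-C14-HSL with only the arrays compared, where the fit had fewer residual degrees of freedom. Without 1 array or experiment the 24 h count after acetone lay between 3915 (without experiment 2) and 7934, and after oxo-C14-HSL between 5120 (without experiment 2) and 8652.

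For the small counts of AHL comparisons the cause of a change was not tested. oxo-C14-HSL against acetone at 0 h, with 0 genes in limma, had 1 after quantile normalization, normexp or slide as a fixed block. This was the unnamed NM_113054 (log2 difference 1.83 to 4.50), also among the 4 with slide as a random block (consensus correlation 0.22). oxo-C10-HSL against C6-HSL, with 2, had 1 after quantile normalization, normexp, with the deposited table or the mean over probes, 11 with slide as a random block, and 0 with slide as a fixed block or only the arrays compared. RGF7 and PTR3 there had limma adjusted p of 0.00724 to 0.969 and 0.0209 to 0.969 over the alternatives. oxo-C14-HSL against C6-HSL, with 0, had NM_113054 alone after quantile normalization, normexp or either slide block, each of which called it against oxo-C10-HSL too. oxo-C14-HSL against oxo-C10-HSL, with 0, had 1 after quantile normalization or the stricter filter, 2 after normexp, the floor or trend and robust, 3 and 10 with slide as a fixed and a random block, and 6 with the replicate block. FRK1 and PTR3 in that comparison had limma adjusted p of 0.024 to 0.448 and 0.024 to 1.0 over the alternatives. The replicate block raised the flg22 counts to between 10852 and 15894. Its changes of call stand beside the genes and lists given with values.

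Leaving out 1 array or experiment gave 0 to 1 genes for oxo-C10-HSL against acetone (1 without the oxo-C10-HSL array of experiment 1 or 2) and for oxo-C14-HSL against acetone at 0 h (1 without the acetone array of experiment 3, or that experiment). It gave 0 to 2 at 2 h of flg22 (2 without the acetone array of experiment 1) and 0 to 2 at 24 h (2 without the oxo-C14-HSL array of experiment 1). The interactions had 0 to 1 (2 h, 1 without the 2 h oxo-C14-HSL array of experiment 1, the 0 h acetone array of experiment 3 or experiment 1; 24 h, 1 without that acetone array). oxo-C10-HSL against C6-HSL had 0 (without any C6-HSL array, or without experiment 1 or 2) to 2. oxo-C14-HSL had 0 to 1 against C6-HSL (1 without the C6-HSL array of experiment 2) and 0 to 1 against oxo-C10-HSL (1 without the oxo-C10-HSL array of experiment 1 or 2, or experiment 3). C6-HSL against acetone had 0 in each.

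With only the arrays compared, LTP4 and ICS1 at 24 h after acetone, KNOLLE at 24 h after oxo-C14-HSL and PR1 between 24 h and 2 h after acetone had limma adjusted p of 0.0545, 0.0673, 0.0517 and 0.0968. These were the highest over the alternatives (lowest 0.00277, 0.00713, 0.000874 and 0.014). The same setting called PR1 and FLS2 at 24 h after acetone (0.0491 and 0.035).

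The photosynthesis list, whose means with the 75th percentile subtracted were -0.217, -0.0241 and -0.0944, changed sign with scaling. In the same order, its mean after quantile normalization, normexp and in the deposited table was 0.0133, 0.0416 and 0.0313 at 24 h after oxo-C14-HSL, 0.209, 0.224 and 0.221 between 24 h and 2 h after oxo-C14-HSL (called higher each time, preset adjusted p 0.0279, 0.0248 and 0.0295, against 0.762 with the percentile), and 0.0263, 0.0212 and 0.0287 for oxo-C14-HSL against acetone at 0 h. Without experiment 3, salicylic acid genes changed sign for oxo-C14-HSL against acetone at 0 h (leave-outs -0.339 to 0.358, and 0.216 without its oxo-C14-HSL array), against oxo-C10-HSL (-0.782 to 0.0885), and in the interactions at 2 h (-0.380 to 0.689) and 24 h (-0.321 to 0.332, and -0.215 without the 0 h oxo-C14-HSL array). So did root markers in the interactions (2 h, -0.0213 to 0.482; 24 h, -0.115 to 0.795), cell cycle at 2 h (-0.413 to 0.0785), flavonoids for oxo-C10-HSL (-0.571 to 0.0713) and heat shock between oxo-C10-HSL and C6-HSL (-0.763 to 0.278, and 0.131 without the oxo-C10-HSL array). Detoxification at 24 h ran from -0.149 (without experiment 2) to 0.383. Why these changed was not tested beyond the leave-outs.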

Other observations

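The correlations between the flg22 times were the only tests here chosen after the result was seen. Between 2 h and 24 h of flg22 after acetone, 10 of 13 low oxygen genes rose and 0 fell (the same when adjusted over the list alone), among them the sucrose synthase gene SUS4 (log2 difference 3.23 ± 0.42, SE from limma), the haemoglobin gene HB1 (2.47 ± 0.24), and PDC1 and SAD6. The list had a mean of 1.85 (1.72, 1.56 and 2.28 by experiment), with an adjusted p of 0.00023 in limma's camera with the preset correlation and adjusted p = 0.285 with an estimated correlation. Genes of pattern receptors and their signalling were lower at 24 h in 11 and higher in 0 of 14 cases (the same when adjusted over the list alone), with the chitin receptor genes CERK1 (-1.62 ± 0.10) and LYK5 (-1.73 ± 0.21), LYK4 (-1.99 ± 0.16), the co-receptor gene BAK1 (-1.35 ± 0.10) and FLS2 (-1.08 ± 0.21). Their mean was -0.92 (-1.0, -0.85 and -0.92 by experiment; adjusted p = 0.0711 with an estimated correlation). Of 24 salicylic acid genes 12 fell and 1 rose (13 and 2 adjusted over the list alone; mean -0.81; adjusted p = 0.438 with an estimated correlation). EDS5, which exports a precursor of salicylic acid from the chloroplast, fell by 2.52 ± 0.18 and the glutaredoxin gene GRX480 by 2.38 ± 0.41, while PR1 was the member that rose over all genes.

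Root markers fell in 9 and rose in 1 of 15 cases (the same when adjusted over the list alone; mean -0.88; adjusted p = 0.45 with an estimated correlation), with the nitrate transporter gene NRT2.1 at -2.11 ± 0.41 and the root hair oxidase gene RBOHC at -1.83 ± 0.18. Flavonoid genes fell in 5 and rose in 0 of 15 cases (the same when adjusted over the list alone; mean -1.35; adjusted p = 0.391 with an estimated correlation). Besides DFR these included LDOX (at least 3.7-fold) and UGT79B1 (at least 9.46-fold). With all 24 arrays required to be above background, this list's mean was -0.559 and its preset adjusted p 0.0859. Auxin response genes, with 4 higher and 9 lower of 22 (the same when adjusted over the list alone), did not pass limma's camera (adjusted p 0.124), yet the auxin-conjugating enzyme genes GH3.3 (-2.57 ± 0.23) and GH3.2 (-2.08 ± 0.17) fell. Heat shock genes did not pass either (adjusted p 0.216; 1 higher and 4 lower of 9, also when adjusted over the list alone), with the chaperone genes HSP90.1 at -3.03 ± 0.35 and HSP70 at -3.00 ± 0.37. Of 9 senescence genes 4 rose, among them SAG13 (1.64 ± 0.39) and DIN1 (1.63 ± 0.26), and 0 fell (the same when adjusted over the list alone; camera adjusted p 0.129).

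The log2 differences between oxo-C14-HSL and acetone were compared across the 25740 genes between times, which share no arrays. They correlated with r = -0.0487 between 0 h and 2 h of flg22, 0.113 between 0 h and 24 h, and 0.171 between 2 h and 24 h. Of the genes 48.5%, 56.2% and 54.8% had the same sign. Genes are not independent replicates, and arrays of the same experiment enter both sides of each correlation, so no p is given.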
